A study of Escherichia coli with 2 samples.

How the data were processed

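The data are lists of R-loop footprints from single-molecule R-loop footprinting sequencing of 2 plasmid libraries, 1 per genotype (WT and G3), prepared from Escherichia coli. Per the labels' protocols, purified plasmids were transcribed in vitro with T3 RNA polymerase, treated with sodium bisulfite under non-denaturing conditions and made into Pacific Biosciences libraries. The submitters' processing notes name Bismark 0.20.0, an aligner and caller for bisulfite reads; its role and settings are not given in the sources used here, nor is the rule by which a run of conversions was called a footprint. That rule sets the shortest footprint that can be seen and where a footprint is cut, and it could differ in effect between inserts whose cytosines differ.

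Each deposited line holds a start and an end position in bp of the plasmid reference, with the read name and strand. The deposited score column, as the authors filled it, is 0 in every line and ranks nothing. Only the plus strand is listed, and read names mark circular consensus reads of 1 sequencing run that both libraries share; no well of that run occurs in both libraries. Molecules without a footprint are not listed. Positions are given here 1-based, and the start is the lower coordinate; the place and direction of the insert and of the T3 promoter within the reference were not used here, since no plasmid sequence was at hand, so no base or gene annotation is given. The 2 libraries were placed on 1 coordinate axis: 66 start positions and 70 end positions occurred in both, against at most 24 and 21 when G3 was moved by any other offset of up to 12 bp. Of 89 start positions in WT, 42 were also end positions, as were 45 of 96 in G3.

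Length, start and end were compared as G3 minus WT by the difference in medians and by the Kolmogorov-Smirnov distance, each with a two-sided permutation test of 100000 resamples over footprints and a percentile bootstrap interval of 10000 resamples, with Benjamini-Hochberg adjustment over 18 tests (3 measures, 2 statistics, all footprints and each of 2 clusters). Coverage was the share of footprints holding the midpoint of each 100 bp window counted from position 1; starts and ends were counted per window. Shares have exact Clopper-Pearson intervals and two-sided Fisher's exact tests, adjusted over the windows with any footprint, with a threshold of 0.05. A share of 0 was given the upper limit of its exact interval. Footprints on 1 molecule, or molecules copied during library preparation, are not independent, and intervals cover counting error only. The similarity of footprints was the share of pairs with a reciprocal overlap of at least 80%. The windows named in the text were fixed by rule before the data were examined: the most covered, the first and last covered by 10% of footprints, the 3 largest coverage differences past the threshold in each direction, and the 3 most used start and end windows of each library. The windows at 701 to 800 and 1501 to 1600 fall outside this rule and were named after their values were seen. The split into clusters (starts up to 700, and 801 to 1100), the single positions and the comparison at equal start positions were added after seeing the data.

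The tests were tested on simulated libraries drawn from the WT footprints, 100 per setting. With 10 percentage points moved to the lesser cluster, the window at 601 was called higher in 95% of simulated comparisons of G3 with WT, with 5 points in 28%, and with none in 0%. An added length of 20 bp was called by the median in 91% of runs and by the Kolmogorov-Smirnov distance in 100%, and one of 10 bp in 41% and 95%. The length was added to every footprint alike, which moves repeated lengths off the values in use. These rates therefore apply to a uniform shift and not to a change in some footprints only. With no change the median called 6% and the Kolmogorov-Smirnov distance 7%.

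Alternatives were 1 footprint per molecule, identical start and end pairs counted once, a minimum length of 200 bp, thinning of the larger library, removal of the outermost footprints, means, other windows, other overlap rules and, added later, the main cluster or single-footprint molecules alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.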

Results

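R-loop footprints were measured on single molecules of a bacterial plasmid, pUC57, that carries the Airn sequence. An R-loop is a structure in which a transcript pairs with the template DNA strand and leaves the other strand unpaired. Airn is an imprinted mouse gene for a long non-coding RNA, and its sequence is a commonly used template for R-loop formation. The plasmid was transcribed in a test tube with T3 RNA polymerase and treated with sodium bisulfite without denaturing the DNA, so that unpaired cytosines were converted and a run of conversions on a long read marks the unpaired strand. There were 2 libraries, 1 with the wild-type insert (WT) and 1 with the insert labelled G3; the label does not say what was changed, and the protocol names an Airn mutant with altered G-stretches. The WT library listed 562 footprints on 531 molecules and the G3 library 698 footprints on 667 molecules. These numbers set the precision: at this depth a count of 0 allows a share of up to 0.654% in WT and 0.527% in G3. With 1 library per genotype no difference has a replicate check, and every p-value compares these 2 libraries of molecules, not the 2 genotypes. Intervals are 95% intervals and cover counting error only.

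Whether footprints fell in the same places in the 2 libraries was the first question. The labels name no untreated library, so it was not measured how many footprints would be listed without transcription. The insert was not placed on the reference, so a cluster cannot be assigned to it. In both libraries the footprints fell into a lesser cluster that began at or below position 700 of the plasmid reference and a main cluster that began between 801 and 1100, and only 3 WT footprints and 0 G3 footprints began in between. A further 9 WT and 25 G3 footprints began beyond 1100. The lesser cluster took a larger share of the G3 footprints: 25.1% of them (175 of 698, exact Clopper-Pearson interval 21.9 to 28.5%) started at or below position 700, against 12.8% in WT (72 of 562, 10.2 to 15.9%). The odds ratio of G3 to WT was 2.28 (1.67 to 3.12; two-sided Fisher's exact test, p = 4.7e-08, adjusted p = 3.1e-07 over 13 shares tested). Starts at 801 to 1100 made up 71.3% of G3 footprints (498 of 698, 67.8 to 74.7%) and 85.1% of WT footprints (478 of 562, 81.8 to 87.9%). These are shares of listed footprints; molecules without a footprint were not listed, so the frequency of R-loops per molecule was not measured here. With a minimum length of 200 bp, which 2 WT and 4 G3 footprints of the lesser cluster reached, the shares differed by 0.36 points and the call ended (Fisher's exact test, p = 1). The 2 clusters were separated at positions chosen after the data had been seen.

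Coverage along the plasmid showed the same 2 clusters and, within the main one, higher coverage of the window at 1001 to 1100 in G3. The window at 901 to 1000 was the most covered in both libraries: its midpoint lay inside 68.5% of WT footprints (64.5 to 72.3%) and 57.7% of G3 footprints (54.0 to 61.4%). The first window covered by at least 10% of footprints was 601 to 700 in WT and 501 to 600 in G3, and the last was 1001 to 1100 in both, with the window at 701 to 800 nearly empty in between (0.53% in WT and 0.57% in G3). Coverage was higher in G3 at 601 to 700 (21.2% against 11.6%, adjusted p = 3.4e-05 by Fisher's exact test), at 501 to 600 (17.6% against 8.19%, adjusted p = 1.0e-05) and at 1001 to 1100 (38.3% against 31.1%, adjusted p = 0.022). It was lower in G3 at 901 to 1000, by 10.8 percentage points, and at 801 to 900, where it was 24.8% against 35.1% (Fisher's exact test, adjusted p = 0.00028 for both). In all, 6 of 13 windows with any footprint differed, 4 higher and 2 lower in G3. The remaining one, 1501 to 1600, held 8 G3 footprints and 0 WT footprints. Among footprints of the main cluster alone, G3 and WT differed by 0.39 points at 901 to 1000 and by -6.65 points at 801 to 900 (Fisher's exact test, adjusted p = 1 and 0.057), and G3 was higher by 17.0 points at 1001 to 1100 (adjusted p = 6.2e-07). The lower coverage of G3 at 901 to 1000 was thus not seen once main cluster footprints alone made up the total. Counting each start and end pair once ended the calls at 501, 601 and 1001 (Fisher's exact test, adjusted p = 0.070, 0.13 and 0.079), with differences of 5.77, 5.11 and 7.55 points. No window was called when the whole window had to be covered, where 801 and 901 differed by -0.10 and -1.61 points, or at a minimum length of 200 bp, where they differed by -10.9 and -7.68 points (Fisher's exact test, adjusted p = 1, 1, 0.55 and 0.35). The sign at 1001 depended on what counts as covered: with any overlap G3 was lower by 3.84 points (Fisher's exact test, adjusted p = 0.26).

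**Figure D1:**
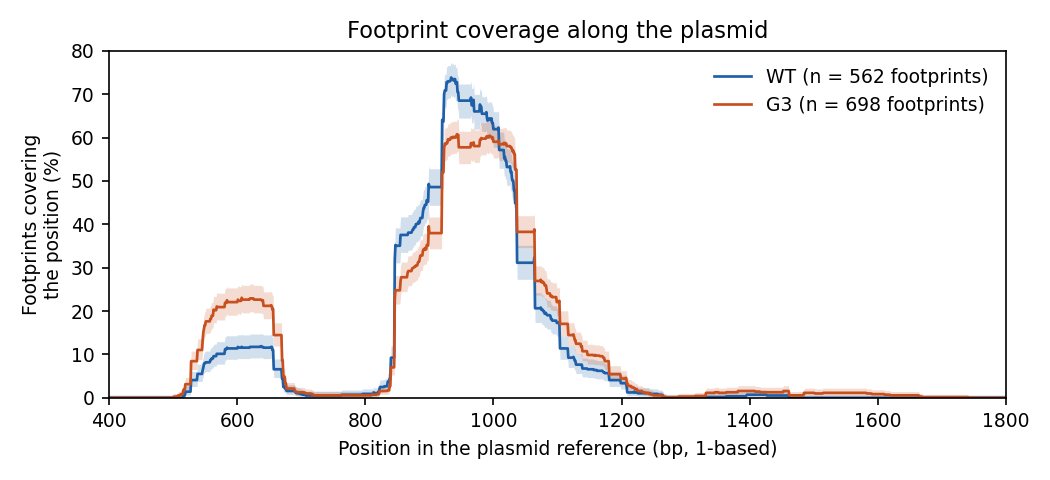
Share of footprints (%) that cover each position (bp) of the plasmid reference from 400 to 1800, for the WT and the G3 library, with bands for exact 95% intervals; 1 G3 footprint that starts at 233 lies outside the axis. At the midpoints of the 100 bp windows, G3 lies above WT at 501 to 700 and at 1001 to 1100, and below WT at 801 to 1000.

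Where footprints began was also compared. Starts were concentrated on a few positions shared by both libraries. Position 846 was the most used, with 127 WT footprints (22.6%) and 110 G3 footprints (15.8%), and position 920 came next with 87 and 98. The 3 most used start windows were 801 to 900, 901 to 1000 and 501 to 600 in both libraries. The window at 501 to 600 took 22.6% of G3 starts and 11.6% of WT starts, and the window at 801 to 900 took 39.8% and 49.5% (Fisher's exact test, adjusted p = 0.0049 for the second), whereas 901 to 1000 took 29.1% and 32.2% (adjusted p = 0.53). The window at 801 to 900 held 278 starts in each library, and its share is of all footprints. Within the main cluster alone 0 start windows were called, so its lower share in G3 is not a start difference separate from that of the lesser cluster. The 5 most used start positions held 53.2% of WT footprints (49.0 to 57.4%) and 45.0% of G3 footprints (41.3 to 48.8%). The median start was 855 in both libraries (interval of the difference -35.5 to 15.0 bp; permutation test, p = 1). The whole distributions differed, with a Kolmogorov-Smirnov distance of 0.123 (two-sided permutation test, p = 0.00011, adjusted p = 0.00040 over 18 tests). Counting each start and end pair once ended these calls: the distance was 0.0888 (permutation p = 0.072) and 0 start windows were called in place of 2. Within the main cluster the distance was 0.067 and did not pass the test (permutation p = 0.12). None of 51 single start positions with at least 5 footprints passed Fisher's exact test after adjustment; 6 had an unadjusted p under 0.05.

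The end of the footprints differed within the main cluster. WT footprints more often had their end between 901 and 1000, while G3 footprints more often had it beyond 1100. The end is the higher coordinate, and the direction of transcription was not used. The window at 901 to 1000 held the ends of 18.9% of WT footprints (106 of 562, 15.7 to 22.3%) and 8.02% of G3 footprints (56 of 698, 6.12 to 10.3%; Fisher's exact test, adjusted p = 2.2e-07). Among footprints starting at 801 to 1100 these shares were 21.8% (104 of 478) and 10.8% (54 of 498; Fisher's exact test, adjusted p = 1.6e-05), and ends beyond 1100 made up 20.3% in WT and 30.9% in G3 (adjusted p = 0.00047). Over all footprints, the most used end window was 1001 to 1100 in both libraries, at 48.0% in WT and 39.4% in G3 (Fisher's exact test, adjusted p = 0.011). It held 270 of 562 WT ends and 275 of 698 G3 ends. The lower share in G3 thus includes the larger share of the lesser cluster, and shows no loss of these ends within the main cluster. The next most used end window was 901 to 1000 in WT and 601 to 700 in G3, the latter at 22.9% against 11.7% in WT. The window at 1101 to 1200 was the third in both (14.2% in WT, 18.3% in G3, Fisher's exact test, adjusted p = 0.19). Of the 3 end windows called, only 901 to 1000 was still called over distinct start and end pairs (-11.3 points, Fisher's exact test, adjusted p = 0.00040), and none at 200 bp or more, where the difference at 901 to 1000 was -0.83 points (adjusted p = 1).

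Single end positions were compared next. The 3 most used ones in WT took shares that did not pass the test between the libraries: position 1036 ended 13.7% of WT and 14.3% of G3 footprints, position 1064 ended 11.7% and 11.9%, and position 1103 ended 6.05% and 5.30% (Fisher's exact test, adjusted p = 0.97, 1 and 0.96). Shares of single positions are of all footprints, of which the lesser cluster made up 25.1% in G3 and 12.8% in WT. Similar shares therefore do not show similar use within the main cluster. Among footprints starting at 846, position 1064 ended 15.0% in WT and 29.1% in G3, and among those starting at 920, 11.5% and 10.2%. Position 1008 ended 29 WT footprints (5.16%) and 6 G3 footprints (0.86%), and was the only one of 52 end positions past the threshold (Fisher's exact test, adjusted p = 0.000325); 14 had an unadjusted p under 0.05. Of 19 tested end positions from 901 up to 1035, 16 took a lower share of footprints in G3, the exceptions being 945, 1029 and 1033. Of 23 from 1036 to 1300, 18 took a higher share. These single positions were compared after the data had been seen.

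**Figure D2:**
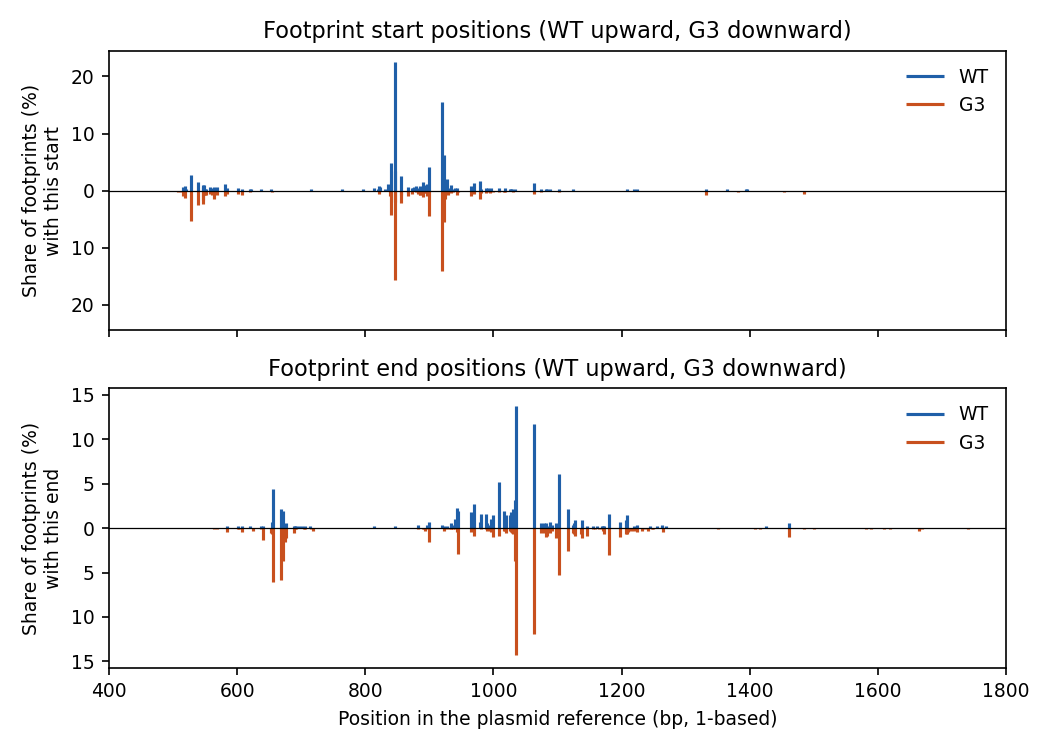
Share of footprints (%) with each start position (upper panel) and end position (lower panel), in bp of the plasmid reference, with WT drawn upward and G3 downward. Starts peak at 846 and 920 in both libraries, and most ends from 943 to 1031, such as 1008, have shorter bars in G3, with 945 an exception.

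The overall end distributions differed by a Kolmogorov-Smirnov distance of 0.127 (permutation test, p = 3.0e-05, adjusted p = 0.00013). The median end was 1033 in WT and 1036 in G3, a difference of 3 bp (0 to 7 bp; permutation p = 0.018, adjusted p = 0.041), whereas the mean end was 19.1 bp lower in G3 (permutation p = 0.070), since the lesser cluster weighs on the mean. Within the main cluster the median end was 1036 in WT and 1064 in G3 and did not pass the test (permutation p = 0.074). The bootstrap interval of this difference, 28 to 28 bp, excludes 0 and so disagrees with the test. Both medians lie on much used end positions, so the median is a coarse measure here. The mean was 23.4 bp higher (14.5 to 32.2 bp; permutation p = 1e-05, the smallest the resamples can give), and the distance between the distributions was 0.217 (permutation p = 1e-05, adjusted p = 6.0e-05).

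Footprint length was compared next. G3 footprints of the main cluster were longer, with a median of 182 bp (174 to 185 bp, n = 498) against 145 bp in WT (138 to 163 bp, n = 478). The difference of 37 bp (19 to 46 bp) passed the permutation test at p = 1e-05 (adjusted p = 6.0e-05), and 32.1% of these G3 footprints reached 200 bp against 20.1% in WT (Fisher's exact test, adjusted p = 7.4e-05). Main cluster length was not compared over distinct start and end pairs. For all footprints it was: the median then differed by 17.5 bp (permutation p = 0.032), and the Kolmogorov-Smirnov distance, 0.0903, did not pass (permutation p = 0.086). Footprints of the lesser cluster had a median of 119 bp in G3 (n = 175) and 118 bp in WT (n = 72), a difference of 1 bp (-7.5 to 12.5 bp; permutation p = 0.67). Over all footprints the length was 158 bp ± 66.3 (SD, n = 698 footprints) in G3 and 147 bp ± 64.1 (SD, n = 562 footprints) in WT. The medians, 145 and 135.5 bp, differed by 9.5 bp (0 to 22 bp; permutation p = 0.016, adjusted p = 0.041), and keeping only the longest footprint of each molecule ended that call (9 bp, permutation p = 0.11). Footprints ranged from 30 to 362 bp in WT and from 37 to 384 bp in G3, and those over 300 bp made up 1.96% and 2.15% (Fisher's exact test, p = 0.84).

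**Figure D3:**
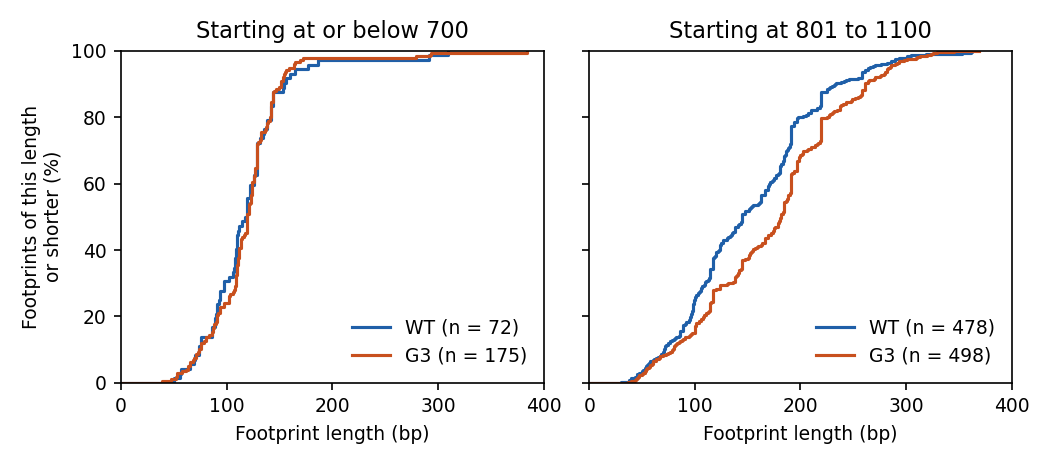
Cumulative share (%) of footprints by length (bp) in the WT and G3 libraries, for the cluster starting at or below 700 (left) and the cluster starting at 801 to 1100 (right). The curves nearly coincide on the left, with medians of 118 and 119 bp, and separate on the right, with medians of 145 and 182 bp.

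Footprints that shared a start position were then compared, so that only their ends could differ. From position 846 the median end was 1029 in WT (n = 127) and 1036 in G3 (n = 110), and the distance between the end distributions was 0.289 (permutation p = 4.0e-05, adjusted p = 8.0e-05 over both starts), while the mean end, 13.5 bp higher in G3, did not pass (permutation p = 0.091). From position 920 the median end was 1036 in WT (n = 87) and 1082.5 in G3 (n = 98), with a distance of 0.222 (permutation p = 0.0084) and a mean end 22.8 bp higher in G3 (permutation p = 0.014). Both start positions were chosen after the data had been seen, as the most used ones.

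**Figure D4:**
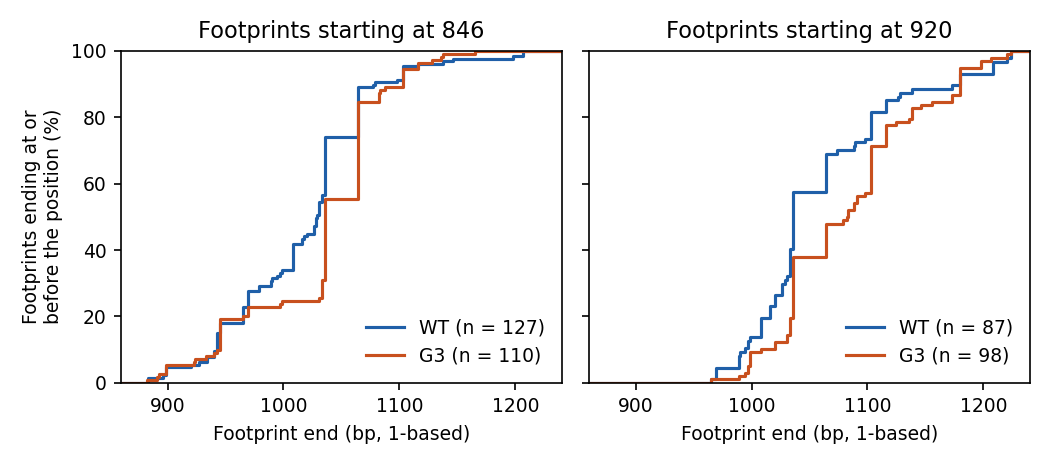
Cumulative share (%) of footprints by end position (bp) for footprints that start at 846 (left) and at 920 (right), in the WT and G3 libraries. From both starts the G3 curve lies below the WT curve around 1031, and both libraries step up at 1036 and 1064.

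Few molecules carried more than 1 footprint. In WT 31 of 531 molecules had 2 (5.84%, 4.00 to 8.18%), and in G3 28 of 667 had 2 or 3 (4.20%, 2.81 to 6.01%). The shares differed by less than the counting error (odds ratio 0.71, 0.40 to 1.24; Fisher's exact test, p = 0.23). Of these molecules, 14 in WT and 17 in G3 carried 1 footprint in each cluster. Continuous footprints that joined the clusters, starting at or below 700 and ending beyond 800, numbered 2 in WT and 4 in G3.

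The likeness of footprints was described by pairs. In WT 8.50% of footprint pairs overlapped reciprocally by at least 80%, against 6.18 to 6.81% over 100 random pairings of the observed starts and lengths. In G3 it was 9.06% against 5.26 to 5.67%, and between the libraries 8.11% against 5.57 to 5.92%. The random pairings do not keep ends on the positions in use or identical pairs together, so an observed share above their range shows no more than that boundaries recur.

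Farther along the plasmid footprints were rare. Those ending beyond 1300 numbered 4 in WT (0.71%) and 20 in G3 (2.87%; Fisher's exact test, adjusted p = 0.0098), and the farthest end was at 1461 in WT and 1741 in G3. The limit at 1300 was chosen after the data had been seen.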

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

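The main cluster and single-footprint settings and the share of the lesser cluster were chosen after seeing the data; the others were planned. With only the longest footprint per molecule, or only single-footprint molecules, the difference in median length was 9 bp and no longer passed (permutation p = 0.11 and 0.13). Counting each start and end pair once left Kolmogorov-Smirnov distances of 0.0903 for length and 0.0888 for start, neither past the threshold, with 3 coverage, 0 start and 1 end windows called in place of 6, 2 and 3. The differences in median length, 17.5 bp, and in median end, 8 bp, still passed in that setting (permutation p = 0.032 and 0.012). Fewer footprints were then tested (334 in WT, 392 in G3). A minimum length of 200 bp left 99 WT and 168 G3 footprints, of which 2 and 4 were in the lesser cluster. No test passed there: the length differed by 9 bp and the end by 22.5 bp in median, the distances were 0.0765 (length), 0.140 (start) and 0.113 (end), the share of the lesser cluster differed by 0.36 points, and 0 coverage, 0 start and 0 end windows were called. Coverage called 2 windows of 200 bp and 0 when the whole window had to be covered. By the mean, the difference in start was -30.2 bp and passed (permutation p = 0.0014), and the end was -19.1 bp, opposite to the median. Within the main cluster the start distance was 0.0665 and the difference in median end 28 bp, both not past the threshold, and 2 coverage and 0 start windows were called. Coverage differences changed sign at 601 with a minimum length of 200 bp (-0.41 points) and with whole windows (-0.25). They also did so at 1001 with that minimum length (-1.91) and with any overlap (-3.84). The cause of these changes was not tested. At 901 the sign changed within the main cluster (0.39), where the lesser cluster, 25.1% of G3 and 12.8% of WT footprints, is left out of the total. Pairs overlapping by 50% made up 36.8% (WT), 32.5% (G3) and 32.7% (between), and by 90% 3.48%, 3.31% and 3.09%. Of 46 values for single windows, 27 kept their call and 19 lost it, the 5 that changed sign included. The other 56 values of the main comparisons kept their side of the threshold, or counts within 1.5 times, as with thinning or without the outermost footprints. Among them the difference in median start, 0 bp over all footprints, had no fixed direction: it was -3 bp over distinct pairs, 20.5 bp at 200 bp or more and 9 bp within the main cluster. A score filter, a choice of strand and a minimum of 400 bp gave no values, since every score is 0, 1 strand is listed and 0 footprints reach that length. No paired analysis was possible because each genotype has 1 library.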

Other observations

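The tests on start positions, neighbouring footprints, missing cytosines and equal starts below were chosen after the result was seen; those on repeated pairs, on length classes and on molecules without a footprint were written down before their own results were seen, although the limit of the lesser cluster at 700 was itself chosen after seeing the data.

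Of the start positions, 30 were used in G3 alone and 23 in WT alone, most by few footprints. The 2 most used of those in G3 alone were 856 and 866. Position 856 began 6 G3 footprints (0.86%) and position 866 began 7, against 0 of 562 in WT, which allows up to 0.654%. Neither passed Fisher's exact test after adjustment over single positions (adjusted p = 0.25 and 0.19). Position 927 showed the opposite, with 11 WT starts (1.96%) and 2 G3 starts (0.29%; Fisher's exact test, adjusted p = 0.070). On molecules with more than 1 footprint the median distance between neighbouring footprints was 94 bp in WT (31 distances, 11 to 277 bp) and 203 bp in G3 (31 distances, 34 to 502 bp). The medians differed by 109 bp (permutation p = 0.036), but the distributions did not pass (Kolmogorov-Smirnov distance 0.323, permutation p = 0.078). Molecules with a footprint in each cluster made up 45.2% of these molecules in WT and 60.7% in G3 (Fisher's exact test, p = 0.30).

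The share of footprints in the lesser cluster was higher in G3. Molecules copied during library preparation would show as repeated start and end pairs, but over distinct pairs the share was still 24.7% in G3 and 15.9% in WT, a difference of 8.88 points (Fisher's exact test, p = 0.0033). The difference over all footprints was 12.3 points, so repeated pairs may account for part of it. Boundaries recur on few positions, so separate molecules can share a pair. Counting pairs once removes such molecules as well as copies, so it does not measure copying. Coverage of the windows at 501 and 601 was no longer called over distinct pairs (Fisher's exact test, adjusted p = 0.070 and 0.13). A difference in footprint length between the libraries is argued against as the whole cause, since over 3 length classes the Mantel-Haenszel odds ratio of G3 to WT was 2.60 (1.91 to 3.55): the share was 33.3% against 14.6% under 100 bp and 31.9% against 15.4% from 100 to under 200 bp, but 2.38% against 2.02% at 200 bp or more, where only 4 and 2 footprints of the cluster remain. Whether more G3 molecules formed R-loops in the lesser cluster, or fewer formed them in the main cluster, cannot be told apart, because 0 molecules without a footprint were listed. The change of insert named by the genotype stays open and untested, since a second library of either genotype was not analysed here.

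Footprints ended less often at 901 to 1000 in G3. Cytosines missing from the G3 insert at these end positions would remove those ends, but 100% of the end positions that at least 5 WT footprints used in the window (9 of 9) still served as a footprint boundary in G3. This covers those 9 positions only. A different mix of start positions is also argued against, because within the main cluster, with each of its 43 shared start positions as a stratum, the Mantel-Haenszel odds ratio of G3 to WT was 0.44 (0.30 to 0.64). From position 846 alone the shares, 29.1% and 19.1%, did not pass (Fisher's exact test, p = 0.095). Cytosines added in G3, or missing from it at other positions, may change where the calling rule cuts a footprint. Neither was tested, since the sequences were not used here, and the insert itself stays open.

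Footprints from positions 846 and 920, which lie 74 bp apart, had 1036 and 1064 among their 3 most used ends in both libraries: 1036 ended 17.3% and 17.2% of them in WT and 24.5% and 18.4% in G3, and 1064 ended 15.0% and 11.5% in WT and 29.1% and 10.2% in G3. Footprints of one typical length would end further along from the later start by that distance, yet those from 920 were shorter in median, in WT (difference -67 bp, interval -74 to -38 bp) and in G3 (difference -27.5 bp, interval -74 to -7 bp). Ends independent of the start are argued against too, more weakly in WT: among ends above 1000, which both starts can reach, the distance between the end distributions was 0.204 in WT (permutation p = 0.019) and 0.382 in G3 (permutation p = 1e-05, the smallest the resamples can give), while the median end differed by 0 bp in WT (interval 0 to 28 bp, permutation p = 1) and by 27 bp in G3 (0 to 55 bp, permutation p = 0.00017). A hypothesis between these, that some end positions are used from both starts and that how often may depend on the start, was not tested separately.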
